A study of Mus musculus with 6 samples.

How the data were processed

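Gene expression was measured in MC3T3-E1 cells, a mouse pre-osteoblast line, after 3 days of culture in 24-well plates on the dealloyed and coated scaffold (De-HA, n = 3) or on the original scaffold (FeMnSi, n = 3). Total RNA of each sample was amplified, labelled with Cy3 and hybridised to 1 Agilent mouse array. The array images were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The signals used are linear intensity values per spot, which per the file headers were background-subtracted and detrended within each array, with a surrogate in place of low signals, and were not scaled between arrays. The authors' series matrix holds log2 values, 1 per probe and array, which the values show to be quantile-normalized: every column has a median of 5.77, and r with the log2 scanner signal of the same array was 0.997 to 1.00. The steps between the scanner signals and the matrix are not given in the sources used here, and the matrix was used only as an alternative.

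Each array carried 44397 spots, of which 1377 were controls, and 39429 different probes. Log2 processed signals were shifted by the 75th percentile of the non-control spots of the array, spots marked by Feature Extraction as non-uniform or population outliers were left out, and the spots of a probe were averaged. Probes well above background on at least 3 of the 6 arrays, whatever the group, were kept; these were 28380, of which 205 were left out because every spot was marked as an outlier on some array. The share of probes well above background was 63.5%, 74.4% and 74.1% on De-HA 1, 2 and 3 and 70.1%, 73.2% and 69.2% on FeMnSi 1, 2 and 3. The 75th percentile of the signal was 624, 654, 582, 654, 720 and 707 in the same order, and no spot was saturated. Probes were named through their RefSeq transcript accession, in the RefSeq gene annotation of assembly GRCm38.p6, where 27219 of the 27751 probes with such an accession matched. Accessions that belong to several genes were not used, and no coordinates were used. In all, 27234 probes carried 1 gene symbol and 12195 carried none; the latter entered no comparison and were tested separately. Of several probes of a gene, the one with the highest mean over all 6 arrays stood for the gene, which left 15535 genes. Of these, 3936 had more than 1 probe, and 1452 had probes whose log2 fold changes differed in sign. Near-identical paralogs, such as the osteocalcin genes, can share a probe, and their values are not separable.

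De-HA was compared with FeMnSi by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with moderated statistics, Benjamini-Hochberg adjustment over all genes tested and an adjusted p threshold of 0.05, and also with a minimum of 2-fold. Files were read with data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene lists, 37 in number and each with at least 5 tested members, were tested by camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members past the threshold were counted with adjustment over all genes and over the list alone. The lists cover osteoblast, osteocyte and other cell type markers, angiogenic factors, matrix, adhesion, the handling of iron and other metals, stress responses, the cell cycle, signalling targets, metabolism and housekeeping genes.

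Genes were named by rule. The 12 largest rises and the 12 largest falls were taken among genes past the threshold with the arrays of the groups apart, well above background on at least 1 array of each group, and with a symbol that is not a clone or predicted model. Up to 4 genes per direction were added that were not well above background on any array of 1 group. Their bound compares the mean of the other group with the higher of the signal and the lowest signal well above background on each array. With signals not well above background raised to that floor, list medians moved most for 4 lists: adipocyte markers (0.35 to 0.33), smooth muscle markers (0.52 to 0.55), hypoxia genes (-0.066 to -0.038) and interferon-stimulated genes (-0.26 to -0.15). In each list up to 4 members past the threshold with the smallest p-values were named, or the 2 smallest where none passed. Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1, Col1a1, Bmp2, Vegfa, Hif1a, Angpt1, Tfrc, Hmox1, Mt1 and Mt2 were named whatever their result. The comparison, the filter, the lists and this rule were set before the data were examined. Ank, Ankrd1, Bglap2, Cnn1, Des, Fhl2, Fos, Jun, Mki67, Msx2, Pmepa1, Srf, Tnc and Tpm1 fall outside it and were chosen after their values were seen, as were the gene families among the additional observations.

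Scan times split the arrays over 2 slides, with 4 arrays (De-HA 1, 2 and 3 and FeMnSi 1) on slide 1 and 2 (FeMnSi 2 and 3) on slide 2. The slide was fitted as a block in an alternative; the estimate is then the De-HA mean minus FeMnSi 1, and FeMnSi 2 and 3 inform the spread alone. Other alternatives were quantile normalization, median scaling, normexp background correction (offset 50) with quantile normalization, the series matrix, no filter on dim probes, probes well above background on all 6 arrays, the mean of a gene's probes, and an intensity trend with robust variances. Further ones were array quality weights, a replicate block, leaving out each array in turn, camera with an estimated correlation, fry, and at least 2-fold with an unadjusted p under 0.05. The array quality weights did not converge and fell almost wholly on FeMnSi 3. Values with them are printed but count neither for nor against a result. Normexp used median spot signals, since no mean signals were in the files used. The arrays of slide 1 alone, keeping spots marked as outliers, and testing named and unnamed probes together were added later. A scan-date block was left out because all arrays were scanned on 1 day.

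The fit was tested on simulated data with the spread of the real arrays and 15535 genes, 50 for each size of change. At log2 fold changes of 0.5, 1, 2 and -1 it recovered 26%, 70%, 94% and 76%, with 9 false calls among 142. With the slide as a block the shares were 0%, 20%, 82% and 28%, with 6 false calls among 71. Camera found the 1 simulated list that was shifted, by -0.5, and none of the others. The simulated genes were independent of each other, so the simulation does not measure the error of the preset correlation. It held no slide difference, so it does not measure the false calls that such a difference would add.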

Results

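The series addresses the expression changes that go with osteogenic and angiogenic differentiation of cells grown on FeMnSi scaffolds, made of an iron, manganese and silicon alloy. RNA came from MC3T3-E1 cells, a mouse pre-osteoblast line that can be driven to lay down mineralised matrix, after 3 days on scaffold in 24-well plates. In the De-HA group (n = 3) the scaffold had been dealloyed, a treatment that leaches part of the metal out of an alloy, and then given a bioactive coating. The FeMnSi group (n = 3) grew on the untreated scaffold and is the reference. Each sample was hybridised to 1 single-colour Agilent mouse array, on which 15535 named genes could be tested. The share of probes well above background ran from 63.5% on De-HA 1 to 74.4% on De-HA 2, and no spot was saturated. The labels do not state whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. By scan time, De-HA 1, 2 and 3 and FeMnSi 1 shared slide 1, while FeMnSi 2 and 3 were on slide 2. Slide 2 holds FeMnSi arrays alone and gives no comparison of its own. The value within slide 1 is the De-HA mean minus FeMnSi 1, equals the estimate with the slide as a block, and stands beside the pooled values.

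The comparison of De-HA with FeMnSi asks what the dealloyed and coated scaffold changes in these cells. Omd, which encodes osteomodulin, a small leucine-rich proteoglycan of bone matrix, was the gene with the largest measured rise, at 5.19-fold (log2 fold change 2.38 ± 0.14 SE, adjusted p = 0.000947, 2.26 within slide 1). Npnt, encoding the integrin ligand nephronectin, rose 4.99-fold (2.32 ± 0.17 SE, adjusted p = 0.00155, 1.98 within slide 1, 1.72 by its other probe). Wif1, a secreted Wnt inhibitor, rose 4.08-fold (2.03 ± 0.12 SE, adjusted p = 0.00114, 1.95 within slide 1). Phex, an endopeptidase of osteoblasts and osteocytes whose loss causes phosphate wasting, rose by 1.66 ± 0.11 on the log2 scale (1.84 within slide 1). The contractile genes Myl9 and Acta2 rose 2.96-fold and 2.91-fold, with 1.37 and 1.63 on the log2 scale within slide 1. The other large rises were in Insc, an adaptor for orienting the mitotic spindle (log2 fold change 1.92), Otor (1.82), the cytokine gene Il22 (1.76), the guidance ligand gene Slit2 (1.69), the amine oxidase gene Aoc3 (1.68) and Rassf2 (1.51). Of these 12 genes, 11 also passed with the slide as a block; Il22 did not, with an adjusted p of 0.0646.

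The largest measured falls were in Ces2e, a carboxylesterase gene, and in Il33, an alarmin cytokine gene (adjusted p = 0.000947, -3.13 within slide 1). Ces2e fell 8.05-fold (log2 fold change -3.01 ± 0.20 SE, adjusted p = 0.00141, -2.83 within slide 1, -2.07 by its other probe). The fitted fall of Il33 was 9.86-fold, or 7.84-fold when its signal on De-HA 1, which was not well above background, is raised to the lowest signal on that array that was. Cst6, which encodes a secreted cysteine protease inhibitor, fell 5.70-fold (-2.51 ± 0.10 SE, adjusted p = 0.000863, -2.62 within slide 1). Car9, the hypoxia-induced carbonic anhydrase gene, fell by 2.06 ± 0.15 on the log2 scale (-1.82 within slide 1). Fabp4, a fatty acid binding protein gene used as an adipocyte marker, fell by 1.99 ± 0.15 (-1.96 within slide 1), and the glutathione transferase gene Gsta3 by 1.97 ± 0.24 (-1.49 within slide 1). The list of 12 was completed by the MHC class II gene H2-Eb1 (-2.59, or -1.88 with its De-HA 1 signal raised in the same way), Plxdc1 (-2.26), the histone gene H4c17 (-2.13), the myeloid receptor gene Trem2 (-1.70), Patl2 (-1.68) and Cyth4 (-1.59). Il33, H2-Eb1, H4c17, Patl2 and Cyth4 were well above background on 2 of the 3 De-HA arrays. H2-Eb1, H4c17 and Patl2 did not pass with the slide as a block, with adjusted p-values of 0.142, 0.0820 and 0.0868.

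**Figure D1:**
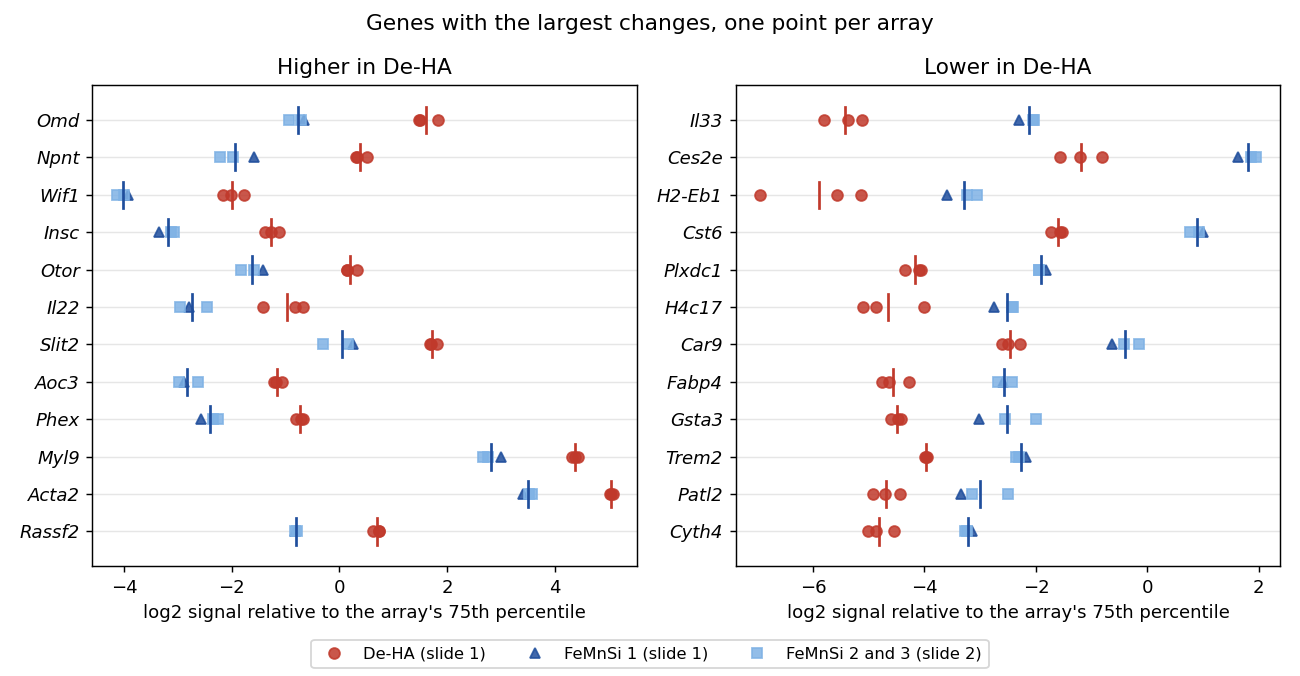
Log2 signal relative to the 75th percentile of each array for the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in De-HA, 1 point per array and a bar at each group mean. Circles are De-HA arrays, triangles FeMnSi 1 from the same slide and squares FeMnSi 2 and 3; for every gene the 3 De-HA arrays lie apart from the 3 FeMnSi arrays, as for Omd with group means of 1.61 and -0.77.

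Some genes were measured in only 1 group, so that their change has only a lower bound. The bound sets the mean of the brighter group against a floor formed from the lowest signals well above background on each array. Mgst1, a microsomal glutathione transferase gene, was not well above background on any De-HA array and was at least 4.47-fold lower. Its adjusted p of 0.000863 in limma belongs to the fitted fall and not to this bound. Kcnh5, a potassium channel gene, was at least 2.38-fold lower, Spib, a transcription factor gene of B cells and plasmacytoid dendritic cells, at least 1.98-fold, and the histone gene H3c1 at least 1.91-fold. In the other direction, Astn1, Olfr486, Slco1a5 and Tmie were not well above background on any FeMnSi array and were at least 2.17-fold, 2.06-fold, 1.84-fold and 1.76-fold higher. Slco1a5 and Tmie did not pass with the slide as a block, with adjusted p-values of 0.0631 and 0.138. The p-values of these genes come from signals not raised to the floor. They rest in 1 group on signals not well above background, and they do not test the bounds.

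In all, limma with Benjamini-Hochberg adjustment placed 1658 of the 15535 genes past an adjusted p of 0.05, 989 higher and 669 lower in De-HA, and 5238 at an unadjusted p under 0.05. Of these, 198 differed at least 2-fold, 100 higher and 98 lower. All 1658 had the same sign within slide 1, but no other outcome was possible. For each of them every De-HA array lay on the same side of every FeMnSi array, and FeMnSi 1 also entered the fit that chose them. With the slide as a block, 194 genes passed (108 higher, 86 lower), 147 of them shared with the 1658, and the arrays of slide 1 alone gave 57. The median log2 fold change of all genes was 0.10, against 0.00 after quantile normalization, and the share of changed genes that were higher was 59.7%, against 42.8% after quantile normalization, 37.3% with median scaling, 41.3% in the series matrix and 44.3% after normexp. The number of genes was 504, 377 and 241 without De-HA 1, 2 and 3, and 4476, 538 and 240 without FeMnSi 1, 2 and 3. At least 2-fold changes numbered 488 without FeMnSi 1 and 124 without FeMnSi 2. Of the 126 genes past the threshold that are named by the rule set in advance, 50 passed in all 6 of these fits. All 126 kept their direction, which was fixed because the arrays of the groups lie apart for each of them. Of the 126, 75, 66 and 56 passed without De-HA 1, 2 and 3, and 126, 74 and 55 without FeMnSi 1, 2 and 3. Named genes that passed in 1 of these fits alone, the one without FeMnSi 1, were Aldh1l2, Alpl, Bbc3, Bnip3, Cacna1c, Col27a1, Creld2, Cryab, Ctsd, Cxcl12, Dnajb9, Dusp1, Esam, Fkbp10, Gbp2, Gdf15, Gpx4, Hfe, Hmox1, Irx5, Kdr, Lyz2, Matn3, Neu1, Nr4a2, Pgk1, Plat, Ptk2, Ptprc, Rpl4, Rpl5, Runx2, Sat1, Sdf2l1, Serpinh1, Slc30a1, Smad6, Sp7, Timp1 and Vegfd. Of those 126 genes, 47 passed with the slide as a block and 114 after quantile normalization.

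**Figure D2:**
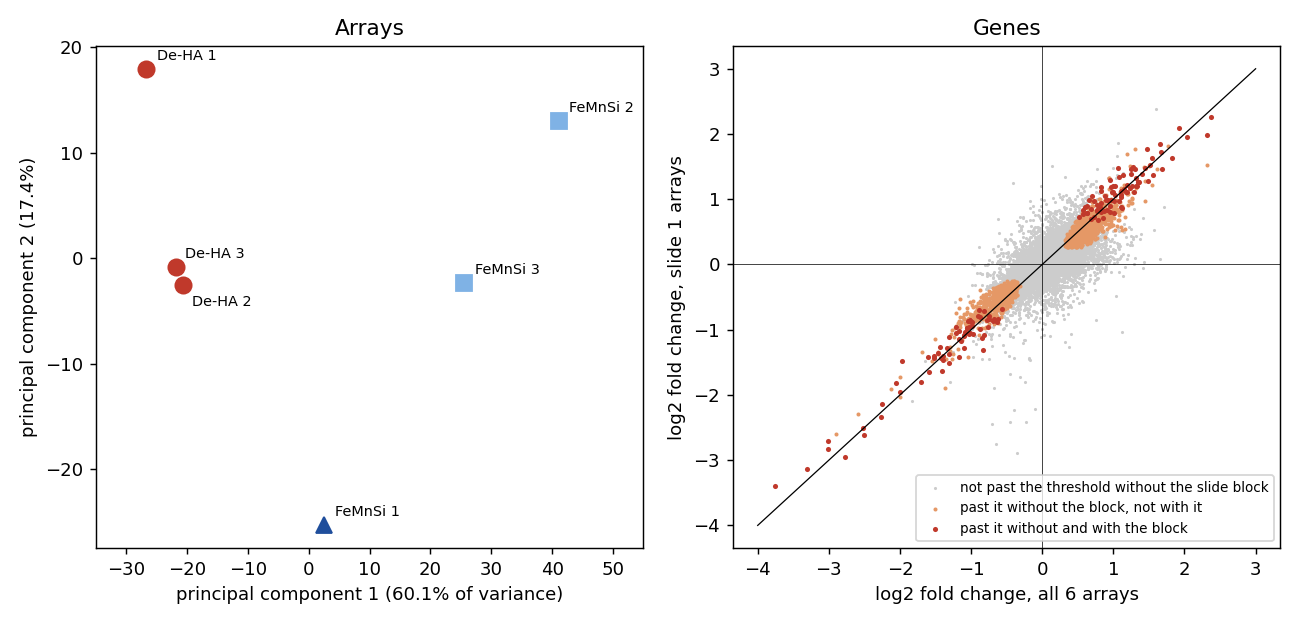
Left, the 6 arrays on the first 2 principal components of the tested genes, which hold 60.1% and 17.4% of the variance: on the first, De-HA arrays lie between -26.7 and -20.6, FeMnSi 1 at 2.56, FeMnSi 3 at 25.6 and FeMnSi 2 at 41.0. Right, 1 point per gene, the log2 fold change over all 6 arrays (horizontal) against that within slide 1 (vertical), with the line of equality; red points are the 147 genes past the threshold without and with the slide as a block.

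Among osteoblast genes, the transcription factor genes Runx2 and Sp7, which direct osteoblast commitment, rose 1.47-fold and 1.56-fold in De-HA (log2 fold changes 0.56 ± 0.11 and 0.64 ± 0.13 SE, adjusted p = 0.0306 and 0.0326, 0.57 and 0.47 within slide 1). Alpl, the tissue-nonspecific alkaline phosphatase gene needed for mineralisation, rose 1.81-fold (0.85 ± 0.15 SE, 0.65 within slide 1), and Ibsp, encoding bone sialoprotein, rose 1.73-fold (0.79 ± 0.11 SE, 0.70 within slide 1), though its 2 probes gave 0.17 and 0.79. Spp1, which encodes osteopontin, went the other way and fell 2.12-fold (-1.08 ± 0.11 SE, adjusted p = 0.00469, -1.03 within slide 1), as did Dmp1, a matrix phosphoprotein gene of osteocytes (-0.79), and Ank, a pyrophosphate transporter gene (-0.43). Col1a1 did not pass (0.44 ± 0.13 SE, adjusted p = 0.0755, 0.08 after quantile normalization). Bmp2 had no probe that passed the filter and was not tested, and Bglap had no probe of its own by accession. Bglap2, the near-identical neighbour of Bglap, gave 0.50 (adjusted p = 0.0521), a value in which the osteocalcin genes cannot be told apart. With the slide as a block, Runx2, Sp7, Alpl and Ibsp did not pass (adjusted p = 0.148, 0.215, 0.141 and 0.0844) and Spp1 did (adjusted p = 0.0461); with median scaling Sp7 did not (adjusted p = 0.0576). Runx2, Sp7 and Alpl each passed in 1 of the 6 fits that leave out 1 array, with adjusted p-values up to 0.108, 0.106 and 0.0804. Of the 26 tested members of the osteoblast list, 10 rose and 3 fell, or 15 and 4 adjusted over the list alone, and 3 and 1 passed with the slide as a block. The list median was 0.45 (0.42 within slide 1, 0.10 after quantile normalization), and camera gave an adjusted p of 0.0577, or 0.560 with an estimated correlation. The camera p passed under each of the 4 other scalings and sources of values (0.0147 to 0.0342), with the slide as a block (0.000735) and on the arrays of slide 1 alone (0.00109). It also passed with probes well above background on all 6 arrays (0.0316) and with the mean of a gene's probes (0.0396). Without 1 array it was 0.170, 0.0341 and 0.0301 for De-HA 1, 2 and 3, and 0.352, 0.00888 and 0.0483 for FeMnSi 1, 2 and 3. It did not pass without the filter on dim probes (0.0519), with an intensity trend (0.0577), with a replicate block (0.105) or with outlier spots kept (0.0592). With array weights, which did not converge, it was 0.344.

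Of 7 tested osteocyte markers, 3 rose, namely Phex, Npnt and Irx5 (0.41), and Dmp1 fell. Sost, Reln and Ptprz1 were on the array but had no probe that was kept. The counts were the same adjusted over the list alone, and camera gave an adjusted p of 0.497 with a median of 0.22 (0.36 within slide 1). Csf1, the macrophage growth factor gene, rose by 0.61 (its 3 probes ran from -0.17 to 0.61), Ccl2 by 0.79 and Cxcl12 by 0.74 (0.11 by its other probe) among 11 tested osteoclast regulators, which made 3 higher, or 4 adjusted over the list alone, with a median of 0.11 (0.07 within slide 1) and a camera adjusted p of 0.424. None of these 3 passed with the slide as a block, where Phex and Npnt did and Irx5 and Dmp1 did not. In the phosphate and calcium list, Vdr, the vitamin D receptor gene, rose 2.83-fold (SE 0.22 on the log2 scale, adjusted p = 0.0131, log2 fold change 1.51 within slide 1) and the calcium channel gene Cacna1c rose by 0.74 (0.46 within slide 1, adjusted p = 0.0551 after quantile normalization); neither passed with the slide as a block (adjusted p = 0.0895 and 0.326). These were 2 of 17 tested members, or 5 adjusted over the list alone, and camera gave an adjusted p of 0.568 with a median of 0.12 (0.20 within slide 1).

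The angiogenic factors did not pass as a group. Vegfa, the main endothelial growth factor gene, gave -0.33 ± 0.13 SE (adjusted p = 0.123, -0.27 within slide 1), and Hif1a gave -0.36 (adjusted p = 0.0825). Angpt1 did not pass (adjusted p = 0.0887) and was not well above background on any De-HA array, so that no fall could be measured against the floor. Of 23 tested members, Ccn2, a matrix-associated growth factor gene, rose 2.12-fold (1.08 ± 0.13 SE, adjusted p = 0.00841, 1.34 within slide 1), Cxcl12 rose by 0.74 (its 2 probes gave 0.11 and 0.74) and the lymphangiogenic factor gene Vegfd fell by 0.56 (-0.46 within slide 1). Epas1, which encodes HIF-2 alpha, passed as higher by 0.78 through its brighter probe, while its other probe gave -1.04, so its direction depends on the probe. Ccn2 was the one of these 4 to pass with the slide as a block as well. Counting Epas1, 3 members rose and 1 fell, or 3 and 3 adjusted over the list alone. The median was 0.06 (0.03 within slide 1, -0.06 after quantile normalization), and camera gave an adjusted p of 0.424 in the lower direction.

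Contractile and cytoskeletal genes were higher in De-HA. Acta2, smooth muscle actin, had the smallest p-value in the smooth muscle and myofibroblast list (1.54 ± 0.08 SE, adjusted p = 0.000947). Myl9 (1.56), Actg2 (1.45, 1.48 within slide 1) and the actin-binding protein gene Tagln (1.36, 1.27 within slide 1) rose beside it. Of 11 tested members 8 rose, or 8 adjusted over the list alone, with 4 past the threshold with the slide as a block and 5 after quantile normalization. The median was 0.52 (0.56 within slide 1, 0.36 after quantile normalization, 0.25 after normexp). Camera gave an adjusted p of 9.79e-06, and an adjusted p of 0.181 with an estimated correlation. Des, the intermediate filament gene of muscle, did not pass (-0.01 ± 0.14 SE). In the list of YAP and serum response factor targets, which shares Acta2, Tagln, Myl9, Tpm1 and Cnn1 with the former, 10 of 22 tested members rose, or 16 adjusted over the list alone, and none fell at an adjusted p of 0.05. The others were Ccn2, the gene for serum response factor Srf (0.78), Fhl2 (0.94), Flna (0.68) and Ankrd1 (0.53). Acta2, Tagln, Myl9 and Ccn2 passed also with the slide as a block. The median was 0.45 (0.43 within slide 1, 0.33 after quantile normalization, 0.26 after normexp), and camera gave an adjusted p of 1.20e-06, or an adjusted p of 0.181 with an estimated correlation.

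In the integrin and focal adhesion list, Parva rose by 0.69 (0.64 within slide 1, its 3 probes from 0.043 to 0.69), Flna by 0.68 and the integrin gene Itga3 by 0.70, while Ptk2, which encodes focal adhesion kinase, fell by 0.45 (-0.49 within slide 1). Of 23 tested members 5 rose and 1 fell, or 10 and 1 adjusted over the list alone, with a median of 0.26 (0.24 within slide 1). Camera gave an adjusted p of 0.0577, against 0.0250 with the slide as a block, 0.0313 on the arrays of slide 1 alone and 0.380 with an estimated correlation. The members named here did not pass singly with the slide as a block (adjusted p = 0.0593, 0.0826, 0.131 and 0.129), nor did any other member. The camera p also passed, at 0.0444 after quantile normalization, 0.0315 after normexp, 0.0448 without the filter on dim probes, 0.0303 with the mean of a gene's probes and 0.0392 without FeMnSi 2. In the remaining settings with the preset correlation it did not, for example at 0.0798 with median scaling, 0.0790 with probes well above background on all 6 arrays and 0.202 with the array weights that did not converge.

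Genes of the matrix moved in both directions. Col8a1 rose 2.37-fold (1.24 ± 0.12 SE, adjusted p = 0.00383, 1.38 within slide 1), Col11a1 by 0.75 (0.68 within slide 1) and Col27a1 by 0.51 (0.58 within slide 1), while Col18a1, whose product yields endostatin, fell by 0.53 (-0.68 within slide 1). Of 21 tested collagens 4 rose and 1 fell, or 6 and 2 adjusted over the list alone (median 0.24, 0.11 within slide 1, camera adjusted p = 0.396). In the collagen processing list, the crosslinking enzyme gene Loxl1 fell by 0.57 (-0.69 within slide 1, -0.16 by its other probe), and the chaperone genes Fkbp10 (0.48) and Serpinh1 (0.35) were higher, but neither passed after quantile normalization, where they gave 0.22 and 0.03, and Serpinh1 gave -0.02 after normexp. That list had 2 of 20 higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.18, 0.02 within slide 1, camera adjusted p = 0.497). Of the genes named so far in this group, Col8a1 and Loxl1 passed with the slide as a block. Among 34 tested matrix proteins other than collagens, 7 rose and 1 fell, or 14 and 2 adjusted over the list alone. The leucine-rich repeat genes Ogn (0.99, 1.20 within slide 1) and Aspn (0.83, 0.94 within slide 1) rose with Omd, as did the microfibril gene Fbn2 (0.68), and Tgfbi fell by 0.74 (-0.58 within slide 1). The median was 0.23 (0.21 within slide 1), with a camera adjusted p of 0.0309, or an adjusted p of 0.237 with an estimated correlation. Omd, Fbn2, Ogn, Aspn and Tnc passed with the slide as a block, and Tgfbi did not. That call ended after quantile normalization (median 0.08, adjusted p = 0.126), after normexp (0.119), in the series matrix (0.0685), with a replicate block (0.0690), without De-HA 2 (0.0526) and without FeMnSi 1 (0.0671). With array weights, which did not converge, the camera adjusted p was 0.0847. Of 19 tested matrix proteases and inhibitors, Plaur (0.47) and Plat (0.35) rose and Mmp19 (-0.87) and Timp1 (-0.49) fell, the same counts adjusted over the list alone. The median was 0.14 (0.06 within slide 1), with a camera adjusted p of 0.854, no protease or inhibitor passed with the slide as a block, and Plaur and Plat did not pass after quantile normalization (adjusted p = 0.0562 and 0.0532).

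Genes of the cell cycle fell together in De-HA. Of 26 tested DNA replication genes 17 fell and none rose, or 23 fell adjusted over the list alone, with a median of -0.67 (-0.57 within slide 1, -0.77 after quantile normalization). The helicase subunit genes Mcm5 (-1.01 ± 0.09 SE, adjusted p = 0.00242, -1.06 within slide 1), Mcm7 (-1.01, -0.88 within slide 1) and Mcm3 (-0.88, -0.99 within slide 1) and the replication fork gene Gins1 (-1.22, -1.04 within slide 1) had the smallest p-values. Of 27 mitosis genes 17 fell and none rose, or 23 adjusted over the list alone, with a median of -0.60 (-0.49 within slide 1, -0.69 after quantile normalization). Among them were Prc1 (-0.83, -0.76 within slide 1), the kinesin genes Kif20a (-0.75) and Kif11 (-0.73), the cyclin gene Ccnb2 (-0.70) and the proliferation marker Mki67 (-0.50). Camera gave adjusted p-values of 7.50e-19 and 4.27e-17 for these lists, and adjusted p = 0.181 and 0.227 with an estimated correlation. With the slide as a block, 6 replication genes and no mitosis gene passed singly, while camera gave 1.46e-18 and 2.32e-13. For p53 targets, of which 20 were tested, Gtse1 (-0.56), Btg2 (-0.98) and the secreted factor gene Gdf15 (-0.68) fell and Bbc3 rose (0.38, not past the threshold after quantile normalization). None of these 4 passed with the slide as a block. That made 1 higher and 3 lower, or 2 and 4 adjusted over the list alone (median 0.04, 0.01 within slide 1, camera adjusted p = 0.435).

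Among signalling lists, Wnt targets and inhibitors were higher. Besides Wif1, the negative feedback gene Axin2 rose 1.93-fold (0.95 ± 0.11 SE, adjusted p = 0.00768, 0.93 within slide 1), Tnfrsf19 by 0.64 (0.65 within slide 1, 0.20 by its other probe) and the secreted Wnt-binding protein gene Sfrp2 by 0.64 (0.79 within slide 1, adjusted p = 0.0586 after quantile normalization). Of 18 tested members 6 rose, or 8 with 1 lower adjusted over the list alone, with a median of 0.39 (0.28 within slide 1, 0.23 after quantile normalization, 0.16 after normexp) and a camera adjusted p of 0.00200, or an adjusted p of 0.181 with an estimated correlation. Wif1 and Sfrp2 passed with the slide as a block, while Axin2 and Tnfrsf19 did not (adjusted p = 0.0581 and 0.0733). The members that rose include both feedback targets and secreted inhibitors of the pathway. In the BMP and TGF-beta list, Id2 (1.01, 0.97 within slide 1) and the inhibitory Smad gene Smad6 (0.65) rose, and the BMP antagonist gene Grem1 (-0.92, -0.76 within slide 1) and Tgfbi fell. Only Id2 among the members passed also with the slide as a block. With Pmepa1 and Msx2, 4 of 21 rose and 2 fell, or 9 and 2 adjusted over the list alone (median 0.34, 0.21 within slide 1, camera adjusted p = 0.341).

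Immediate early genes, which respond within minutes to serum and stress, were lower. Fosl1 (fold 2.15, SE 0.09 on the log2 scale, adjusted p = 0.00219, -1.08 within slide 1), the RNA-binding protein gene Zfp36 (-1.03, -1.07 within slide 1), the phosphatase gene Dusp1 (-1.04, -1.41 within slide 1), Fos (-1.19, -1.29 within slide 1), Jun and Btg2 fell, and the nuclear receptor gene Nr4a2 rose (0.86, 0.51 within slide 1). Fosl1 and Zfp36 passed also with the slide as a block, the other 5 did not. That was 6 lower and 1 higher of 22, or 8 and 1 adjusted over the list alone, with a median of -0.41 (-0.80 within slide 1, -0.14 with the array weights that did not converge). Camera gave an adjusted p of 1.58e-05, or an adjusted p of 0.502 with an estimated correlation. Interferon-stimulated genes were lower as well, with 8 of 22 tested members past the threshold, or 9 adjusted over the list alone, and none higher. Ifit3 (-0.99, -0.79 within slide 1), Gbp3 (-0.71, -0.77 within slide 1), Oasl2 (-1.22, -0.95 within slide 1) and Gbp2 (-0.46, -0.42 within slide 1) had the smallest p-values, and none of the 8 passed with the slide as a block. The list median was -0.26 (-0.32 within slide 1, -0.12 after normexp, -0.17 without De-HA 1, and -0.15 with signals not well above background raised to the floor), with a camera adjusted p of 3.81e-05, or an adjusted p of 0.227 with an estimated correlation. Of 19 tested NF-kappaB inflammatory genes, Tnfaip3, a feedback inhibitor of that pathway (0.81, 0.88 within slide 1), Csf1 and Ccl2 rose (Tnfaip3 alone also with the slide as a block), or 5 with 2 lower adjusted over the list alone (median 0.11, 0.11 within slide 1, camera adjusted p = 0.541).

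Of genes that handle iron, Cp, which encodes the ferroxidase ceruloplasmin, rose 2.15-fold (SE 0.11 on the log2 scale, adjusted p = 0.00508, log2 fold change 1.12 within slide 1). Slc40a1, the gene of the iron exporter ferroportin, fell 1.92-fold (-0.94 ± 0.13 SE, adjusted p = 0.0121, -0.80 within slide 1), and Hmox1, encoding the haem-degrading oxygenase, fell 1.46-fold (-0.54 ± 0.10 SE, adjusted p = 0.0256, -0.46 within slide 1), followed by Hfe (-0.38). With the slide as a block Cp passed, while Slc40a1, Hmox1 and Hfe did not (adjusted p = 0.0923, 0.161 and 0.0960), and Hmox1 passed in 1 of the 6 fits that leave out 1 array. Tfrc, the transferrin receptor gene, gave -0.18 ± 0.16 SE (adjusted p = 0.436, 0.08 within slide 1, its 3 probes from -0.18 to 0.15). Of 19 tested members 1 rose and 3 fell, or 2 and 3 adjusted over the list alone (median -0.09, -0.04 within slide 1, camera adjusted p = 0.190). Neither metallothionein tested by name passed, with 0.15 for Mt1 and 0.33 for Mt2 (adjusted p = 0.273 and 0.102), and Mt1 turned to -0.09 after quantile normalization. In the list of metallothioneins with zinc and manganese transporters, the zinc exporter gene Slc30a1 rose by 0.55 (0.54 within slide 1, adjusted p = 0.154 with the slide as a block), 1 of 10 tested, or 1 with 1 lower adjusted over the list alone (median 0.17, 0.08 within slide 1, -0.03 after quantile normalization, camera adjusted p = 0.918).

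Antioxidant genes controlled by NRF2 or using glutathione were lower, led by Gsta3, Gsta4 (-1.16, -0.96 within slide 1), the quinone reductase gene Nqo1 (-0.94, -0.77 within slide 1) and Hmox1, with Gpx4 (-0.36); Gsta3 alone passed also with the slide as a block. Of 24 tested members 5 fell and none rose, or 7 fell adjusted over the list alone; the median was -0.30 (-0.13 within slide 1, -0.44 after quantile normalization). Camera gave an adjusted p of 1.16e-05, or an adjusted p of 0.262 with an estimated correlation. Among 14 ferroptosis regulators, Sat1 rose (0.54) and Gpx4 fell, or 1 and 2 adjusted over the list alone (median 0.14, 0.12 within slide 1, camera adjusted p = 0.854). Of 32 hypoxia and glycolysis genes, Car9, Car12 (-1.27, -1.01 within slide 1) and Pgk1 (-0.62) fell and the mitophagy gene Bnip3 rose (0.98, 0.72 within slide 1, with its 3 probes from -0.36 to 0.98), the same counts adjusted over the list alone. Of these 4, Car9 passed with the slide as a block. That list had a median of -0.07 (-0.06 within slide 1, -0.038 with dim signals raised to the floor) and a camera adjusted p of 0.118, which was 0.00489 after quantile normalization, 0.00285 after normexp, 0.00592 in the series matrix and 0.0200 with the mean of a gene's probes. In the other settings with the preset correlation it was 0.0519 to 0.318, and with an estimated correlation 0.502. The endoplasmic reticulum chaperone and unfolded protein list had 3 of 18 lower, Sdf2l1 (-0.45), Creld2 (-0.37) and Dnajb9 (-0.39, or -0.24 by its other probe), or 3 adjusted over the list alone, with a median of -0.14 (-0.22 within slide 1). Camera gave an adjusted p of 0.00644, or an adjusted p of 0.262 with an estimated correlation and 0.0661 without FeMnSi 1. No member of that list passed singly with the slide as a block, nor of the ATF4, heat shock and ferroptosis lists. Among 18 ATF4 targets only Aldh1l2 passed (-0.42; median 0.05, -0.03 within slide 1, camera adjusted p = 0.424), also 1 lower adjusted over the list alone. Among 12 heat shock genes only Cryab passed (0.54, or 0.30 by its other probe; median 0.00, 0.02 within slide 1, camera adjusted p = 0.465), or 1 higher and 2 lower adjusted over the list alone.

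Ribosomal protein genes were higher in the main scaling, with 16 of 27 past the threshold adjusted over the list alone but only Rpl4 (0.54) and Rpl5 (0.48) over all genes. The median of 0.33 (0.17 within slide 1) became 0.01 after quantile normalization, -0.01 after normexp and -0.00 in the series matrix. Camera gave an adjusted p of 0.000285, or an adjusted p of 0.502 with an estimated correlation and 0.977 after quantile normalization. In the lysosome and autophagy list, Gpnmb (-1.16, -1.42 within slide 1) and the protease gene Ctsd (-0.45) were among those that fell, and Neu1 rose (0.34, not past the threshold after quantile normalization). Gpnmb alone passed also with the slide as a block. Of 26 tested members 1 was higher and 3 were lower, or 5 and 5 adjusted over the list alone (median -0.03, 0.01 within slide 1, camera adjusted p = 0.380, 0.0314 after normexp and 0.502 with an estimated correlation). No member of the cholesterol biosynthesis list (24 tested, median 0.03, -0.02 within slide 1) or of the respiratory chain list (26 tested, median 0.07, 0.06 within slide 1) passed in limma, also adjusted over the list alone. Their smallest adjusted p-values were 0.0523 for Srebf2 (0.33) and 0.0653 for Ebp (0.33) in the former and 0.0558 for Uqcrfs1 (0.35) and 0.0876 for Ndufv2 (0.35) in the latter, and camera gave 0.974 and 0.819. Of 15 housekeeping genes, Gusb (-0.47) and Pgk1 fell, also adjusted over the list alone. The median was -0.11 (0.07 within slide 1, -0.23 after quantile normalization), with a camera adjusted p of 0.390, against 0.00384 after quantile normalization, 0.00163 after normexp, 0.00475 in the series matrix and 0.541 with an estimated correlation. The members of the ribosomal and housekeeping lists named here did not pass with the slide as a block.

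The lists of endothelial, macrophage, adipocyte and chondrocyte markers did not pass in camera. Kdr (0.41) and Esam (0.60) were higher among 5 tested endothelial markers, or 3 with 1 lower adjusted over the list alone. The list has 12 markers on the array, of which Cdh5, Tek, Tie1, Vwf, Emcn, Erg and Cldn5 had no probe that was kept. Esam lay near the floor, with group means of -4.57 in De-HA and -5.18 in FeMnSi, where the lowest signals well above background were -4.82 to -5.89. The median was 0.37 (0.38 within slide 1), with a camera adjusted p of 0.541, and Esam did not pass after quantile normalization (adjusted p = 0.0534). Among 9 macrophage and osteoclast markers, Adgre1 (0.78, 0.86 within slide 1) and Ptprc (0.56) were higher and the lysozyme gene Lyz2 (-0.39) was lower, or 4 and 1 adjusted over the list alone (median -0.04, -0.09 within slide 1, camera adjusted p = 0.967). Ptprc did not pass after quantile normalization. Of 9 adipocyte markers Fabp4 alone passed, also adjusted over the list alone, with a median of 0.35 for the list (0.13 within slide 1, camera adjusted p = 0.974). Of 8 chondrocyte markers Col2a1, the cartilage collagen gene, rose 2.17-fold (1.11 ± 0.09 SE, adjusted p = 0.00242, 1.03 within slide 1) and Matn3, not well above background on any De-HA array, was at least 1.21-fold lower, also adjusted over the list alone. The median was 0.17 (0.01 within slide 1, camera adjusted p = 0.965). Of the genes named from these 4 lists, Fabp4 and Col2a1 passed with the slide as a block.

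**Figure D3:**
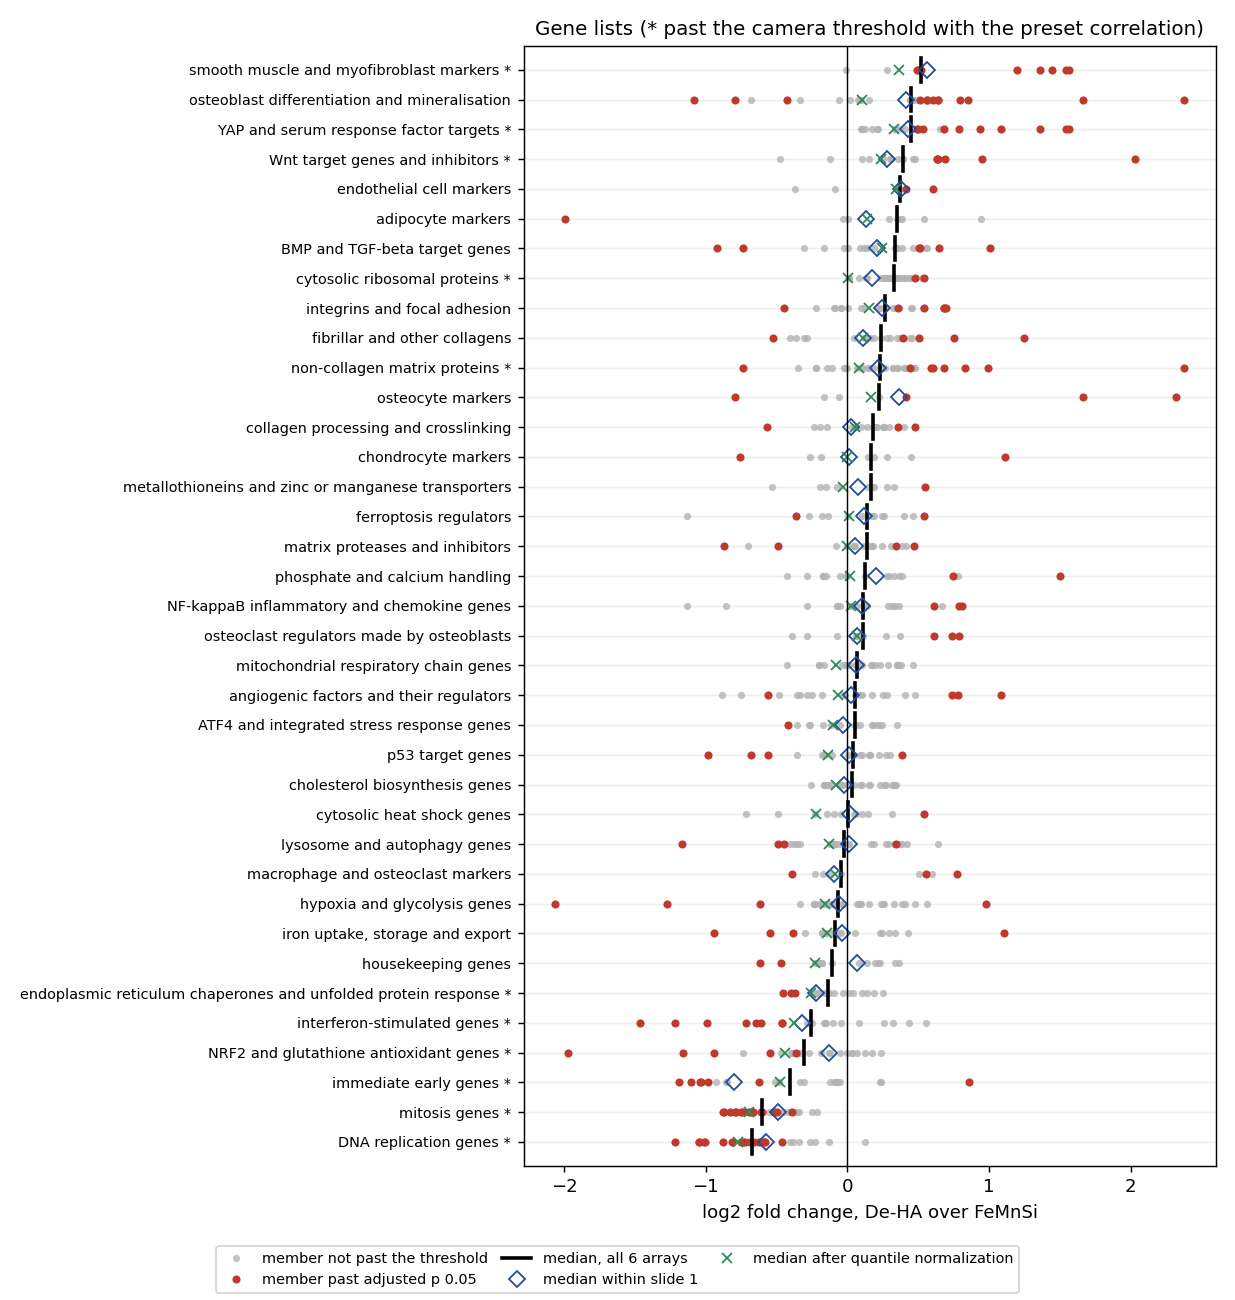
Log2 fold changes of De-HA over FeMnSi for the tested members of the 37 gene lists, 1 point per gene, red where past an adjusted p of 0.05 over all genes. Black bars are list medians over all 6 arrays, diamonds the medians within slide 1 and crosses those after quantile normalization; the medians run from -0.67 for DNA replication to 0.52 for smooth muscle markers, and the ribosomal median lies at 0.33, or 0.01 after quantile normalization.

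With the preset correlation, camera placed 11 of the 37 lists past an adjusted p of 0.05, 5 higher and 6 lower; with the slide as a block it placed 7 higher and 6 lower, and with an estimated correlation none, the lowest adjusted p being 0.181. Camera compares a list with all other genes, and its direction opposed the sign of the median for the angiogenic, metallothionein, ferroptosis, ATF4, heat shock, p53 and cholesterol lists.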

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

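The splits of the arrays were chosen before the data were examined; the tests of the slide, of the scaling and of admixed cells, and the comparison of probes without a gene name, were chosen only after the results they address were seen. Among 7922 probes without a gene name that were well above background on at least 3 arrays, data that no comparison between the groups uses, 215 passed an adjusted p of 0.05 in limma, 167 higher and 48 lower in De-HA, and 2535 had an unadjusted p under 0.05. Among those well above background on all 6 arrays, probe A_55_P2288285 had the largest rise at 4.56-fold (log2 fold change 2.19 ± 0.15 SE, adjusted p = 0.00319, 1.89 within slide 1), followed by A_55_P2065919 at 2.84-fold (1.51, adjusted p = 0.0221). The largest falls were in A_55_P2145136 (-1.34, adjusted p = 0.0171) and A_55_P1954698 (-1.22, adjusted p = 0.0268). No explanation for these probes was tested.

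The number of genes past the threshold, 1658, was weighed against chance and against the slides; the difference between the scaffolds stays open and untested. The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05; the real split alone, 1 of the 10, gave as many genes, and the highest of the others gave 0 in limma, with 98 to 1614 genes at an unadjusted p under 0.05. A slide difference as the whole cause is argued against for 147 genes, which passed in the same direction with and without the slide as a block. It is also argued against for the genes lower in De-HA as a set: of genes called lower from 2 De-HA arrays against FeMnSi 2 and 3, 72.8% to 95.5% were lower on the left-out De-HA array than on FeMnSi 1, above the limit of 70%, against 40.8% to 44.0% of all genes. For the genes higher in De-HA the same shares were 69.2% to 81.6%, against 56.0% to 59.2% of all genes, so outside the 147 it cannot be told apart from the groups. The sizes shrank within slide 1. With De-HA 1, 2 and 3 left out, the median of genes called lower went from -0.56, -0.77 and -0.93 to -0.21, -0.45 and -0.65. That of genes called higher went from 0.57, 0.78 and 0.88 to 0.22, 0.21 and 0.40. A part played by the slide stays open, and it was not separated from shrinkage through the choice of genes.

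The rise of contractile genes and the fall of cell cycle genes were weighed as 1 pattern. A slide difference as the whole cause is argued against by the arrays of slide 1, where each De-HA array differed from FeMnSi 1 by at least 0.418 in the median of the smooth muscle, DNA replication and mitosis lists, in the pooled direction. These differences share FeMnSi 1 as their only reference, so they are not independent, and a deviation of that array would enter all of them. FeMnSi 1 minus the mean of FeMnSi 2 and 3 had medians of 0.13, -0.04 and -0.17 in these lists, on the side of De-HA. Scaling that depends on intensity is argued against as the whole cause by the medians after quantile normalization, which were still 0.36, -0.77 and -0.69. Among 10000 random lists per list, matched on mean expression, the smooth muscle median lay at percentile 99.84, and the replication and mitosis medians at percentile 0. These percentiles decide little alone, because members of a list can be correlated and random genes ignore this. The housekeeping and osteoblast lists, which camera did not call, lay at percentiles 0.01 and 100. Both groups are described as MC3T3-E1 cells, a line, and no source of smooth muscle cells is named. The marker genes by themselves cannot tell smooth muscle cells mixed into the De-HA cultures from a rise in the studied cells. Des did not rise with Acta2 (upper 95% limit of its log2 fold change 0.33, against a lower limit of 1.34) and Myh11 was well above background on 1 De-HA array and on 0 FeMnSi arrays, but both lay near the floor. A response of the cells to the scaffold remains a hypothesis, found and tested on the same arrays, and cell density was not measured.

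The higher ribosomal protein genes may reflect scaling that depends on intensity. Their median lay at percentile 93.3 of 10000 lists matched on mean expression, inside the central 95%. The median log2 fold change was 0.29 in the dimmest decile of genes and 0.22 in the brightest, against 0.06 and -0.01 after quantile normalization. The ribosomal call ended after quantile normalization, where the list median moved from 0.33 to 0.01. A biological cause was not tested.

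Of the same 10 splits of the arrays, again too few for a share under 0.05, the real one alone (1 split) gave as many as 11 gene lists in camera with the preset correlation, and the highest of the others gave 8. Each of the other splits still sets 2 arrays of 1 scaffold against 1 on either side, so part of the difference between the scaffolds enters it. Whether that is why lists passed in those splits was not tested. It was not separated from a preset correlation that is too low, which would make the camera p-values too small. The estimated correlation had a median of 0.025 over the lists and a highest value of 0.448.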

How the results depend on the processing

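The arrays of slide 1 alone, the spots marked as outliers kept, and the probes without a gene name tested together with the genes were chosen after seeing the data; the other alternatives were planned. Genes past the threshold numbered 1561 after quantile normalization, 1569 in the series matrix, 1222 with median scaling, 1884 after normexp, 2023 with probes well above background on all 6 arrays, 1685 with the mean of a gene's probes, 2464 with an intensity trend, 1668 with marked spots kept and 1546 with unnamed probes, all within 1.5 times the 1658. The split by direction moved: 456 higher with median scaling, 648 higher in the series matrix, 1049 lower after normexp (with 54 changed at least 2-fold) and 1540 higher with an intensity trend. Without the filter on dim probes 519 genes passed (285 higher, 234 lower), with more genes tested. Array quality weights gave 10493 (6992 higher, 3501 lower, 342 at least 2-fold), but the weights did not converge and put 57.8 on FeMnSi 3. These counts, and the list values given with array weights, are therefore not used to judge any result. At least 2-fold with an unadjusted p under 0.05 gave 243 (138 higher, 105 lower), by construction another criterion.

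With a replicate block 648 genes passed (380 higher, 268 lower), 542 of them shared with the 1658. After each group's mean was subtracted per gene, De-HA and FeMnSi arrays of the same number correlated at 0.00700, -0.106 and 0.115. Arrays of different number correlated at -0.250 to 0.226. These values show no pairing by number, but with 3 arrays per group they cannot settle it. With the slide as a block 194 passed (108 higher, 86 lower; 115 at least 2-fold), and on the arrays of slide 1 alone 57 (33 higher, 24 lower, 57 at least 2-fold). Both rest on FeMnSi 1 as the only reference array, which is assumed to vary like the others. In simulation the block recovered 20% of changes of 1 on the log2 scale, against 70% without it. That simulation held no slide difference, so it cannot tell lost power from a slide difference taken out by the block. A scan-date block was not run, since all arrays were scanned on 1 day.

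Leaving out each array in turn gave 240 to 4476 genes, 127 to 3065 higher, 96 to 1411 lower and 124 to 488 at least 2-fold. The highest counts came without FeMnSi 1 (4476, of which 1654 were shared with the 1658), the FeMnSi array on the slide of the De-HA arrays. Over the tested genes FeMnSi 1 correlated at 0.991, 0.993 and 0.993 with De-HA 1, 2 and 3. With FeMnSi 2 and 3 it correlated at 0.989 and 0.994, so it lay about as near to De-HA as to its own group. The other counts were 504, 377 and 241 without De-HA 1, 2 and 3, and 538 and 240 without FeMnSi 2 and 3. Lists past the threshold numbered 9 to 13.

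With an estimated correlation, camera called 0 lists (0 higher, 0 lower), whereas fry called 21 (16 higher, 5 lower) and camera with the preset correlation 11. Of these 11, 9 still passed after quantile normalization, after normexp and in the series matrix, 10 with array weights and with a replicate block, 11 with the slide as a block, on slide 1 alone and with median scaling, and 10 in fry, where the immediate early list did not pass. The lists of smooth muscle, YAP, Wnt, NRF2, interferon, DNA replication and mitosis genes passed in every setting but the estimated correlation.

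Of 126 named genes past the threshold, 114 still passed after quantile normalization and after normexp, 113 in the series matrix, 109 with median scaling, 75 without the filter, 77 with a replicate block, 47 with the slide as a block and 26 on slide 1 alone. The direction reversed for Serpinh1 after normexp (-0.023), and for Epas1 with the mean of its probes (-0.13), which by construction adds a probe of the other sign. Unless a reason is given, the cause was not tested. Signal over background limits the dim genes: on De-HA 1 only 63.5% of probes were well above it, and where a group lies below it only a bound on the change can be given.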

Other observations

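The tests in this part were all chosen only after the results were seen. Glutathione S-transferase genes and replication-dependent histone genes recurred among the largest falls. Of 20 tested glutathione S-transferases 7 were lower and 0 higher in limma, 16 were negative, and the median was -0.16 (-0.17 within slide 1, -0.27 after quantile normalization). Of 42 tested histone genes 6 were lower and 0 higher, 33 were negative, and the median was -0.21 (-0.20 within slide 1, -0.33 after quantile normalization). Medians were also negative with median scaling (-0.24 and -0.30), after normexp (-0.24 and -0.24) and in the series matrix (-0.27 and -0.35). Camera gave unadjusted p-values of 1.73e-06 and 2.45e-08, or 0.0157 and 0.00777 with an estimated correlation; these families were picked because members had fallen.

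Slc40a1 and Hmox1, which rise with iron and haem, were lower in De-HA, although neither passed with the slide as a block, and a candidate explanation is a lower iron exposure of the cells on De-HA. Lower iron would raise Tfrc, whose mRNA is stabilised when iron is low, and 1.5-fold was set as the limit. The upper 95% limit of the Tfrc fold was 1.14, or 1.42 with the slide as a block, which argues against a 1.5-fold rise of Tfrc by the probe used. The 3 probes of Tfrc ran from -0.18 to 0.15 on the log2 scale. Tfrc also follows proliferation, and the cell cycle lists were lower, which was not separated. The test therefore cannot decide whether the cells on De-HA met less iron.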
